A study of Mus musculus with 22 samples.

How the data were processed

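The series measured RNA of microglia sorted by flow cytometry from whole brains of C57BL/6J mice of both sexes at 3 ages. Complementary DNA was made with the SMARTer v4 kit and libraries with the Nextera XT kit, per the labels. How the first strand was primed is not given in the sources used here. The submitters' processing notes name FastQC 0.67, Trim Galore 0.4.3, STAR 2.5.2, MultiQC 1.5.0, DESeq2 1.32.0, R 4.1.0 and the genome build mm10. The tool that counted reads and the gene annotation are not given in the sources used here.

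The deposited file holds 1 signal value per gene symbol and library, which the authors made by dividing read counts by 1 size factor per library. This was tested on the values: 100% of them are whole multiples of a step fitted to the low values of their library, the value of 1 read, within a tolerance of 0.01 reads, with a largest distance of 8.14e-05. Whole reads per gene were recovered in that way, and their sum is the depth given for each library. Values are called normalized counts below. Mitochondrially encoded genes and several immediate early and macrophage genes are not analysed here.

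Libraries were grouped by the sex and age in the labels, and none was left out. The labels do not say whether each library came from a single animal, so p-values measure only the spread between libraries. Replicate numbers were not treated as pairs. The mean correlation of residuals was 0.00706 for libraries of different groups with the same number and -0.00162 for those with different numbers.

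Genes with a normalized count of 10 or more in at least 3 libraries were tested, 12552 of 18072. Values were taken as log2 of the normalized count plus 1. A single model with 6 group means was fitted with limma 3.58.1 (trended empirical Bayes, two-sided) in R 4.3.3. From it came 13 comparisons: females against males at each age and on average, the 3 age steps in each sex, and the difference between the sexes in each age step. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison, with a threshold of 0.05. Negative binomial counts were simulated with the means and dispersions of these libraries for 3 of the comparisons, none with an aged group. These were the sexes in young adults, the sexes at middle age, and middle-aged against young adult females. Of genes changed 2-fold 63 to 78% were recovered and of genes changed 4-fold 84 to 89.9%, with 1.27 to 3.51% of calls false. In the simulation genes varied independently, and each unchanged gene had 1 mean normalized count over all libraries. Shifts of many genes together within a library were not simulated, so these shares need not hold for the real comparisons.

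Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 37 lists, 33 had at least 3 members tested. They cover microglial states, immune and metabolic pathways, genes of the sex chromosomes and markers of other cell types. A count is also given with p-values adjusted over the list alone. The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The study's own gene lists are not used here.

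The rule names, for each comparison, up to 8 genes higher and 8 lower with the largest change among genes that pass, with a mean of at least 50 normalized counts in the higher group and no overlap between the groups. The overlap condition is dropped for the average and the differences between the sexes, and predicted genes, clones and pseudogenes are left out. It adds up to 4 members of each list described, the sex-linked genes in the sex comparisons, and in any comparison Apoe, Clec7a, Spp1, Cst7, Itgax, Lpl, P2ry12, Tmem119, Cx3cr1, Sall1, Il1b, Tnf, H2-Aa, H2-D1, Ifit3, C3, C4b, Cdkn1a and Cdkn2a. From the genes that the rule allows, 346 values were taken forward. Those printed in the report were picked from them after their behaviour under the alternatives had been seen, so the closing section gives the tally over all 346.

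The alternatives were a pseudocount of 0.25 or 8, no filter on low values, TMM factors, each library rescaled to the same total, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, a fit of only the groups compared, replicate number as a block, and leaving out each library in turn. A further 3 were chosen after seeing the data: leaving out aged female 1, aged male 1 and middle-aged female 2 together, removing a trend of transcript length and GC content per library, and thinning all libraries to the lowest depth of 17.7 M reads. Transcript length, GC content and positions (mm10) came from the reference annotation, matched by symbol for 97.2% of the genes tested. No fold is given where a group had 3 reads or fewer in all or in each of its libraries, except for the differences between the sexes of Gnat1, Hist1h2ac and Rab7b in the closing section, and intervals and floors, where used, cover counting error only. Results of some genes are not reported here, though counts of genes include them.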

Results

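RNA sequencing measured gene expression in microglia, the resident macrophages of the brain, sorted from whole mouse brain as CD11b-positive, CD45-low, lineage-negative cells. The series sets females against males at 3 ages to ask how sex acts on microglia as the brain grows older. The 22 libraries fall into 6 groups: 3 from young adult females and 3 from young adult males (6 to 10 weeks), 5 from middle-aged females and 5 from middle-aged males (50 to 54 weeks), and 3 from aged females and 3 from aged males (96 to 104 weeks). Libraries are named here by group and replicate number. The recovered depth ran from 17.7 to 34.4 M reads per library. Group means lay between 19.8 ± 1.89 M (SD, n = 3, aged females) and 28.6 ± 3.53 M (SD, n = 5, middle-aged males). Of the 18072 genes in the table, 12552 were tested. Below, normalized counts are means ± SD, log2 fold changes are given ± SE of the fit, and n is the number of libraries just stated.

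Transcripts of the sex chromosomes followed the labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 3.36 normalized counts in any of the 11 female libraries and at least 186.5 in each of the 11 male libraries. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), was at most 5.80 in males and averaged 3485 ± 1531 in females. Middle-aged female 2 stood apart with 42.4 normalized counts of Xist, against 2321 in the next lowest library of its group, and had 0 reads of the 4 Y-linked genes.

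On the first principal component (15.4% of the variance) the 8 libraries of young adult and middle-aged males lay between 20.8 and 64.6, and the other 14, the 3 aged males among them, between -54.2 and 1.25, as the plot of the libraries shows. Comparisons of young adult or middle-aged males with any other group cross this gap. Those among females, between young adult and middle-aged males, and between aged females and aged males do not. On the second component (12.5% of the variance) the 3 young adult females lay between 54.0 and 74.8, and every other library at 21.8 or below. Comparisons of young adult females with any other group span that second separation.

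**Figure D1:**
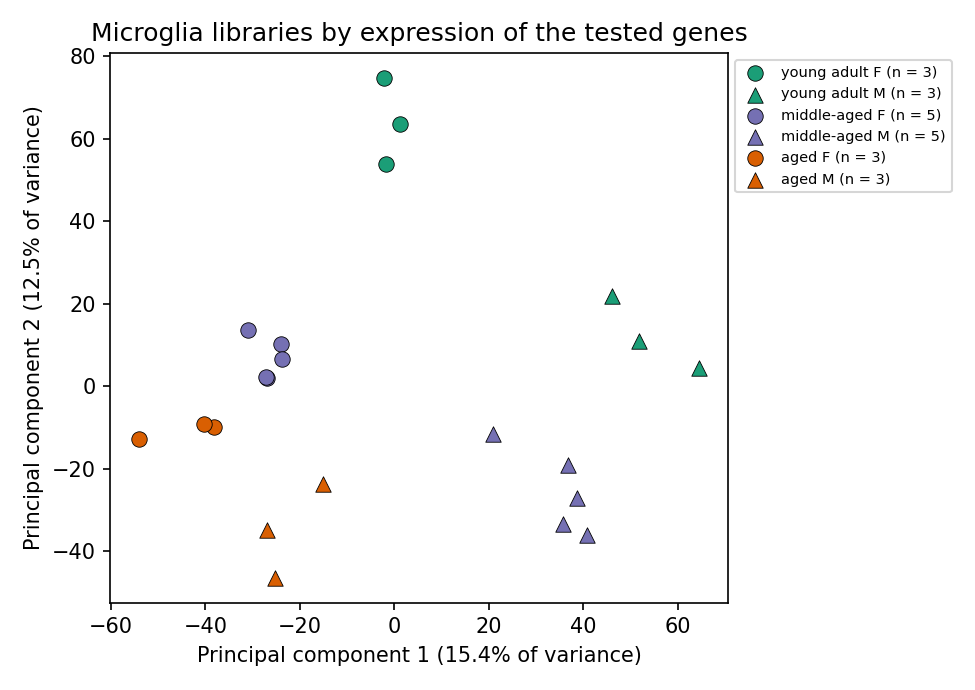
Libraries on the first and second principal components of log2 expression of the tested genes, with colour for age and shape for sex (F, female; M, male). The 8 libraries of young adult and middle-aged males lie at 20.8 or above on the first component, and the other 14 at 1.25 or below.

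Counts of genes called between 2 groups ran from 54 between aged females and aged males to 2701 between middle-aged females and middle-aged males, as the bars of genes called show. The grid of gene lists shows which groups of genes moved in which comparison.

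**Figure D2:**
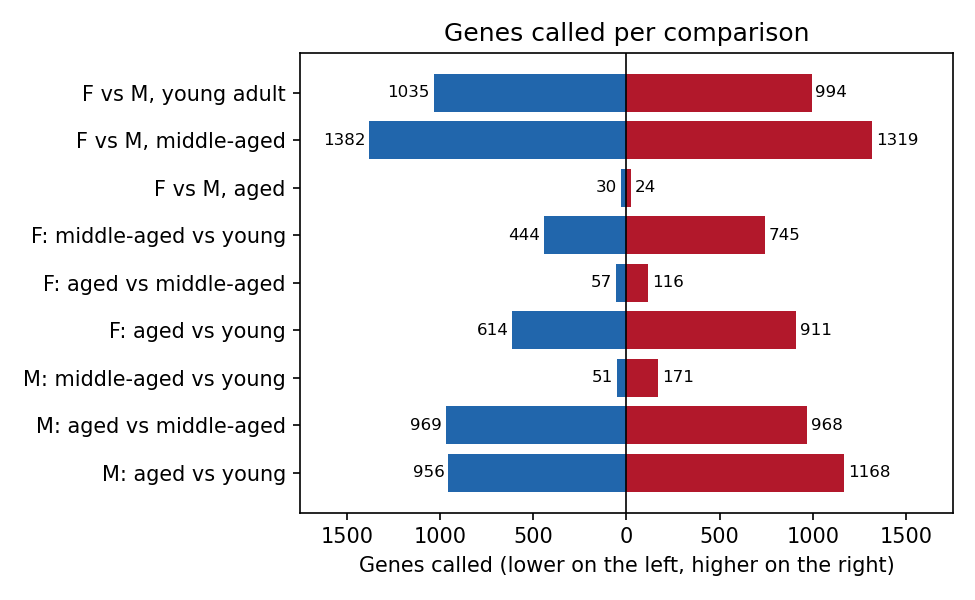
Genes with an adjusted p under 0.05 in each pairwise comparison; bars to the right count genes higher in the first-named group, bars to the left genes lower in it, with the number at each bar. Aged females and aged males differ by 24 genes higher and 30 lower in females.

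**Figure D3:**
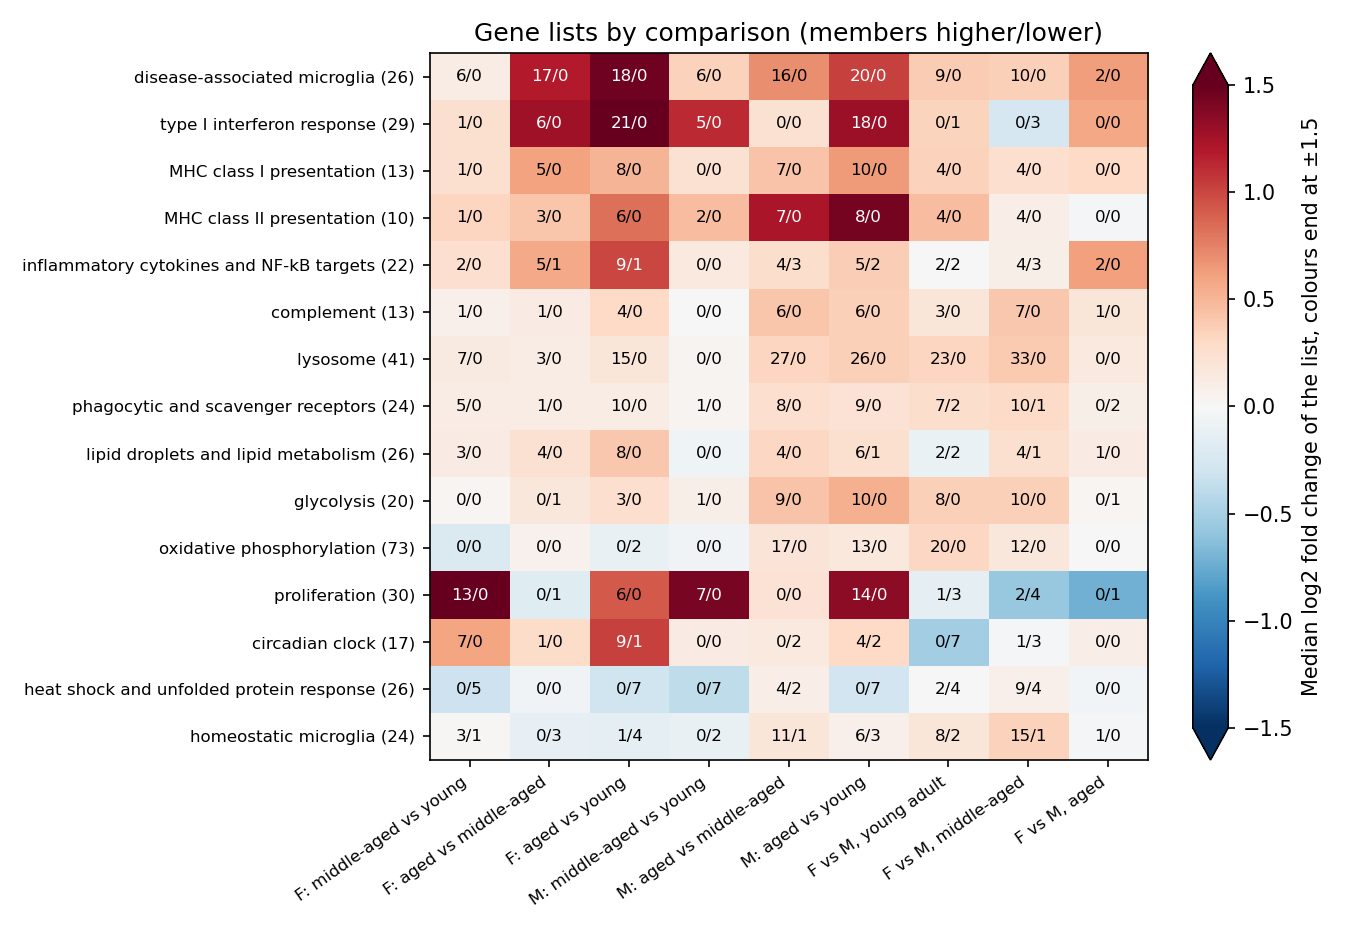
Median log2 fold change of 15 gene lists (colour) in the 9 pairwise comparisons, with the members called higher/lower in each cell and the number of members tested behind each name. The disease-associated list has no member called lower in any of these comparisons.

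What changes in female microglia between young adulthood and old age was asked first. Genes of disease-associated microglia, the state described around plaques and in degenerating tissue, rose strongly. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188), averaged 63743 ± 17572 normalized counts in aged and 6992 ± 1036 in young adult females, a log2 fold change of 3.16 ± 0.34 (adjusted p = 1.12e-06). Spp1 (osteopontin, 4.71 ± 0.80, adjusted p = 3.67e-04), Axl (a receptor for dying cells, 2.97 ± 0.40, adjusted p = 2.22e-05) and Cst7 (a protease inhibitor, 2.79 ± 0.25, adjusted p = 4.82e-08) rose with it. So did Itgax (2.76 ± 0.38, adjusted p = 3.50e-05), Clec7a (a receptor for fungal glucans, 2.17 ± 0.25, adjusted p = 3.18e-06) and Lpl (lipoprotein lipase, 1.53 ± 0.33, adjusted p = 0.00314). In all, 18 of the 26 disease-associated genes rose and none fell, 21 when adjusted over the list alone. Camera gave an adjusted p of 1.47e-16 (adjusted p = 0.0259 with an estimated correlation).

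Interferon and antigen presentation genes were also higher in aged than in young adult females. Of 29 genes of the type I interferon response 21 rose, 25 when adjusted over the list alone. Among them were the nucleic acid sensor Zbp1 (3.07 ± 0.49, adjusted p = 1.90e-04) and Ifit3 (2.40 ± 0.42, adjusted p = 4.60e-04). The camera adjusted p was 5.60e-14 and the call was lost with an estimated correlation (adjusted p = 0.145). MHC class I presentation had 8 of 13 members higher, 9 when adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.145 with an estimated correlation). H2-D1 rose by 1.39 ± 0.19 (adjusted p = 2.79e-05). Class II had 6 of 10 higher on both counts (camera adjusted p = 1.26e-05, adjusted p = 0.0787 with an estimated correlation). The invariant chain Cd74 rose by 2.29 ± 0.21 (adjusted p = 1.28e-07) and H2-Aa by 5.20 ± 1.11 (adjusted p = 0.00319). In the same comparison 5 of 9 markers of border-associated macrophages and 2 of 5 of monocytes were higher. The chemokine genes Ccl4 (2.34 ± 0.25, adjusted p = 1.12e-06) and Ccl3 (2.29 ± 0.28, adjusted p = 4.81e-06) headed the inflammatory list. In it 9 of 22 rose and 1 fell, and 14 rose and 2 fell when adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.0096 with an estimated correlation). Complement C4b rose by 3.17 ± 0.55 (adjusted p = 4.46e-04) in a list with 4 of 13 higher, 6 when adjusted over the list alone (camera adjusted p = 0.00361, adjusted p = 0.163 with an estimated correlation).

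Clock genes formed a further group, with 9 of 17 higher and 1 lower in aged females, 11 and 2 when adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.0096 with an estimated correlation). Per2 rose by 4.09 ± 0.69 (adjusted p = 3.41e-04), Per3 by 1.49 ± 0.24 (adjusted p = 2.62e-04) and Tef by 1.10 ± 0.15 (adjusted p = 2.42e-05). Lysosomal genes rose in 15 of 41 cases, 18 with 1 lower when adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.196 with an estimated correlation). The amounts were small, such as 0.62 ± 0.09 (adjusted p = 6.71e-05) for the protease gene Ctsb. Heat shock and unfolded protein genes fell in 7 of 26 cases, 10 when adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.234 with an estimated correlation). The log2 fold change of Manf was -0.73 ± 0.12 (adjusted p = 2.27e-04). Among 24 homeostatic genes 1 rose and 4 fell, 1 and 10 when adjusted over the list alone (camera adjusted p = 0.00745, adjusted p = 0.264 with an estimated correlation). The purine receptor P2ry12 was lower (-0.54 ± 0.10, adjusted p = 8.81e-04), as was Fcrls (-0.56 ± 0.09, adjusted p = 2.44e-04). Tmem119 (-0.04 ± 0.09, adjusted p = 0.804), Cx3cr1 (-0.06 ± 0.09, adjusted p = 0.728) and the transcription factor Sall1 (-0.01 ± 0.11, adjusted p = 0.978) did not pass. The rod transducin Gnat1 averaged 148 ± 32.1 normalized counts in young adult females and had 0 reads in aged females.

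In total 911 genes were higher and 614 lower in aged than in young adult females, and 29.0% of genes had values that did not overlap between the 3 and 3 libraries, where chance gives 10%. The count of 1525 was 956 without aged female 1, which carried the neutrophil transcript S100a9 at 639 normalized counts, and 962 without young adult female 4. It was 902 when only these 6 libraries were fitted, where H2-Aa (adjusted p = 0.126) and Per2 (adjusted p = 0.0506) no longer passed.

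Between middle and old age in females 116 genes were higher and 57 lower. Apoe stood at 8361 ± 3837 normalized counts in middle-aged and 63743 ± 17572 in aged females (3.03 ± 0.31, adjusted p = 4.23e-06). Lpl (2.13 ± 0.29, adjusted p = 3.13e-04), Cd74 (1.91 ± 0.19, adjusted p = 4.23e-06) and Cst7 (1.67 ± 0.22, adjusted p = 2.00e-04) rose. Among signalling genes Ccl4 (1.67 ± 0.23, adjusted p = 2.93e-04), Ccl3 (1.46 ± 0.25, adjusted p = 0.0027) and the growth factor Csf1 (1.29 ± 0.19, adjusted p = 9.04e-04) rose. The disease-associated list had 17 of 26 members higher and none lower, 20 when adjusted over the list alone (camera adjusted p = 9.58e-26, adjusted p = 0.00842 with an estimated correlation). Inflammatory genes rose in 5 of 22 cases and fell in 1, 10 and 1 when adjusted over the list alone (camera adjusted p = 3.63e-07, adjusted p = 0.00501 with an estimated correlation). Lipid genes rose in 4 of 26, 5 when adjusted over the list alone (camera adjusted p = 4.77e-05, adjusted p = 0.0118 with an estimated correlation). Of the 29 interferon genes 6 rose, and 24 when adjusted over the list alone (camera adjusted p = 4.10e-20, adjusted p = 0.0962 with an estimated correlation). Homeostatic genes fell in 3 of 24 cases, 8 when adjusted over the list alone (camera adjusted p = 1.16e-05, adjusted p = 0.106 with an estimated correlation). Fcrls had -0.41 ± 0.08 (adjusted p = 0.0119). Lars2, a mitochondrial tRNA ligase gene, fell from 24745 ± 4593 to 9665 ± 332 normalized counts (-1.34 ± 0.16, adjusted p = 7.44e-05).

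This count rested on single libraries. It was 21 without aged female 1 and 99 without middle-aged female 2, the library with low Xist and with S100a9 at 652 normalized counts, and 27 without these and aged male 1 together. Without aged female 1, Fcrls had an adjusted p of 0.107, and with replicate number as a block the count was 52. Fcrls did not pass with the block or without the 3 libraries that stand apart. In the fit without these 3, Spp1 (adjusted p = 0.136), Itgax (0.29), Axl (0.124) and Clec7a (0.0505) did not pass either. Nor did Ifit3 (0.151) and H2-D1 (0.195). The list counts of this step were not taken again without these libraries.

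The step from young adult to middle-aged females held more genes, 745 higher and 444 lower. Proliferation genes rose in 13 of 30 cases, 20 when adjusted over the list alone (camera adjusted p = 1.30e-08, adjusted p = 0.145 with an estimated correlation). Top2a (4.31 ± 0.85, adjusted p = 0.00236), Ccnb2 (2.77 ± 0.57, adjusted p = 0.00332) and Mcm2 (1.30 ± 0.25, adjusted p = 0.00195) were among them. The mitotic kinase Plk1 averaged 34.0 ± 13.99 normalized counts in middle-aged and 3.38 ± 5.85 in young adult females. Clock genes rose in 7 of 17, 9 when adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.145 with an estimated correlation). Per2 rose by 2.93 ± 0.61 (adjusted p = 0.00399) and Nr1d1 by 1.54 ± 0.33 (adjusted p = 0.00488). Kcnj12, a potassium channel gene, stood at 429 ± 101 against 16.1 ± 11.6 normalized counts (4.82 ± 0.56, adjusted p = 5.38e-06). The scaffold gene Dlg5 had 101 ± 49.1 against 7.41 ± 11.97 (4.70 ± 0.68, adjusted p = 9.31e-05). Tgfb1 (0.81 ± 0.11, adjusted p = 4.46e-05) and the scavenger receptor Stab1 (0.89 ± 0.11, adjusted p = 2.24e-05) were higher. The receptor genes Gpr165 (-2.17 ± 0.23, adjusted p = 1.32e-06) and Ccr1 (-1.95 ± 0.41, adjusted p = 0.00433) were lower. Heat shock and unfolded protein genes fell in 5 of 26, 9 when adjusted over the list alone (camera adjusted p = 6.73e-06, adjusted p = 0.507 with an estimated correlation). Of the disease-associated genes 6 of 26 rose, 9 when adjusted over the list alone (camera adjusted p = 0.0485, adjusted p = 0.542 with an estimated correlation). Cst7 rose by 1.12 ± 0.22 (adjusted p = 0.00233) and Apoe differed by 0.13 ± 0.31 (adjusted p = 0.844). The total of 1189 was 636 without young adult female 4, 735 without young adult female 1 and 792 with replicate number as a block.

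In males the same 3 steps were taken. Aged males differed from young adult males in 1168 genes higher and 956 lower, a comparison that crosses the gap on the first component. Disease-associated genes rose in 20 of 26 cases with none lower, 22 when adjusted over the list alone (camera adjusted p = 1.17e-15, adjusted p = 0.0496 with an estimated correlation). Axl rose by 3.02 ± 0.40 (adjusted p = 1.24e-05), Cst7 by 2.43 ± 0.25 (adjusted p = 3.49e-07), Itgax by 1.94 ± 0.38 (adjusted p = 0.00118) and Clec7a by 1.63 ± 0.25 (adjusted p = 9.78e-05). Apoe rose from 9680 ± 3343 to 28044 ± 12872 normalized counts (log2 fold change 1.498 ± 0.34, adjusted p = 0.00406), and Lpl differed by 0.72 ± 0.33 (adjusted p = 0.137). Class II presentation had 8 of 10 members higher, 9 when adjusted over the list alone (camera adjusted p = 9.99e-11, adjusted p = 0.0298 with an estimated correlation). H2-Aa rose by 6.26 ± 1.11 (adjusted p = 4.30e-04) and Cd74 by 2.43 ± 0.21 (adjusted p = 5.09e-08). Class I had 10 of 13 higher, 11 when adjusted over the list alone (camera adjusted p = 1.43e-08, adjusted p = 0.0843 with an estimated correlation). The interferon list had 18 of 29 on both counts (camera adjusted p = 4.25e-09, adjusted p = 0.269 with an estimated correlation), Ifit3 at 2.31 ± 0.42 (adjusted p = 5.03e-04).

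Lysosomal genes rose in 26 of 41 cases in aged against young adult males, 33 when adjusted over the list alone (camera adjusted p = 5.14e-15, adjusted p = 0.0606 with an estimated correlation), Man2b1 by 0.82 ± 0.09 (adjusted p = 1.44e-06). Proliferation genes rose in 14 of 30, 20 when adjusted over the list alone (camera adjusted p = 2.74e-10, adjusted p = 0.0496 with an estimated correlation). Glycolytic genes rose in 10 of 20, 15 when adjusted over the list alone (camera adjusted p = 3.27e-07, adjusted p = 0.0505 with an estimated correlation), Pkm by 0.75 ± 0.10 (adjusted p = 1.87e-05). Ribosomal protein genes had 31 of 75 higher and 1 lower, 36 and 2 when adjusted over the list alone (camera adjusted p = 1.22e-08, adjusted p = 0.296 with an estimated correlation). Tmem119 rose by 0.40 ± 0.09 (adjusted p = 0.00239) while P2ry12 (-0.05 ± 0.10, adjusted p = 0.798) and Sall1 (0.08 ± 0.11, adjusted p = 0.681) did not pass. Of the homeostatic genes 6 of 24 rose and 3 fell, 6 and 4 when adjusted over the list alone (camera adjusted p = 0.149). The stress-response gene Zfp36 fell by 1.72 ± 0.13 on the log2 scale (adjusted p = 4.82e-09) and the chaperone Hsp90ab1 by 1.17 ± 0.21 (adjusted p = 3.90e-04). Cdkn1a, a cell cycle inhibitor, rose by 1.02 ± 0.30 (adjusted p = 0.020). Its adjusted p was 0.117 without young adult male 4 and 0.072 without aged male 4. Neutrophil transcripts stood at high levels in aged males 1 and 4 alone of the males, S100a9 at 1000.2 and 1085.5 normalized counts and Ltf at 746.6 and 1438. Both were at 0.987 in aged male 2. Against young adult males S100a9, Ltf and Lcn2 each lost the call in 5 of the 6 fits without 1 library, when only the 6 libraries were fitted and with replicate number as a block. In all, 4 of 7 neutrophil markers were higher in aged males, 6 when adjusted over the list alone (camera adjusted p = 0.00287, adjusted p = 0.296 with an estimated correlation).

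The count of 2124 was 1241 without young adult male 2 and 696 when only the 6 libraries were fitted, where Tmem119 (adjusted p = 0.066), Hsp90ab1 (adjusted p = 0.0738) and Cdkn1a (adjusted p = 0.083) no longer passed; nor did Tmem119 with the transcript length and GC trend removed (adjusted p = 0.0931). With each library rescaled to the same total, which moved the median of all genes by -0.11, 772 genes were higher and 1500 lower, lysosomal genes rose in 19 of 41 cases, and the median of the homeostatic list changed sign, from 0.07 to -0.04.

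From middle to old age, males had 968 genes higher and 969 lower, again across the gap. Homeostatic genes rose in 11 of 24 cases and fell in 1, 12 and 2 when adjusted over the list alone (camera adjusted p = 5.15e-05, adjusted p = 0.158 with an estimated correlation). Tmem119 rose from 107360 ± 7019 to 159950 ± 13328 normalized counts (0.57 ± 0.08, adjusted p = 3.07e-05). Disease-associated genes rose in 16 of 26, 25 when adjusted over the list alone (camera adjusted p = 1.69e-12, adjusted p = 0.0516 with an estimated correlation). In the same comparison 5 of 7 neutrophil markers rose, with S100a9 and Ltf high in aged males 1 and 4 but not in aged male 2. Apoe rose by 1.61 ± 0.31 (adjusted p = 0.00101), Cst7 by 1.16 ± 0.22 (adjusted p = 9.75e-04) and Trem2, a lipid-sensing receptor, by 0.54 ± 0.09 (adjusted p = 2.00e-04). Lpl (0.78 ± 0.29, adjusted p = 0.0737) and Clec7a (0.61 ± 0.23, adjusted p = 0.0688) did not pass, though Clec7a did without middle-aged male 3 (adjusted p = 0.0168) or aged male 4 (adjusted p = 0.0277) and with replicate number as a block, and both did with the length and GC trend removed. Class II genes rose in 7 of 10, 8 when adjusted over the list alone (camera adjusted p = 7.56e-08, adjusted p = 0.0516 with an estimated correlation). Complement genes rose in 6 of 13, 8 when adjusted over the list alone (camera adjusted p = 5.52e-05, adjusted p = 0.0647 with an estimated correlation). C3 rose by 4.07 ± 0.80 (adjusted p = 0.00131) and C1qa by 0.62 ± 0.08 (adjusted p = 3.68e-05). Lysosomal genes rose in 27 of 41, 29 when adjusted over the list alone (camera adjusted p = 1.54e-15, adjusted p = 0.0516 with an estimated correlation). Nfkbiz (-2.61 ± 0.35, adjusted p = 3.47e-05), Lime1 (-4.40 ± 0.60, adjusted p = 3.68e-05) and the histone gene Hist1h2ac (-3.75 ± 0.74, adjusted p = 0.00131) fell. Genes higher in aged males had a median transcript length of 2706 bases and genes lower 4014.5. Fitting only the 8 libraries left 1137 genes. Rescaling to equal totals, with the median of all genes moved by -0.14, gave 440 higher and 1801 lower, with 7 homeostatic genes higher and 4 lower and 16 lysosomal genes higher.

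Young adult and middle-aged males lie on the same side of the gap, and 171 genes were higher and 51 lower at middle age. Proliferation genes rose in 7 of 30 cases, 18 when adjusted over the list alone (camera adjusted p = 3.56e-18, adjusted p = 0.017 with an estimated correlation). Ccnb2 rose by 3.46 ± 0.57 (adjusted p = 8.15e-04) and Ccna2 by 2.59 ± 0.41 (adjusted p = 5.49e-04). Kcnj12 stood at 382 ± 62.4 against 8.12 ± 7.16 normalized counts (6.09 ± 0.56, adjusted p = 3.33e-07). Dlg5 had 170.5 ± 76.1 against 1.74 ± 0.747 normalized counts (adjusted p = 8.38e-06). Interferon genes rose in 5 of 29, 21 when adjusted over the list alone (camera adjusted p = 8.45e-14, adjusted p = 0.197 with an estimated correlation), Zbp1 by 2.42 ± 0.44 (adjusted p = 0.00219). Middle-aged male 3 was far above its group for Ifit3 (1323 against at most 528 normalized counts) and Rsad2 (559 against at most 155). With only these groups fitted, Rsad2 (adjusted p = 0.166) and Ifit3 (0.256) lost the call. Disease-associated genes rose in 6 of 26, 11 when adjusted over the list alone (camera adjusted p = 1.51e-05, adjusted p = 0.273 with an estimated correlation), the tetraspanin Cd9 by 0.55 ± 0.09 (adjusted p = 4.74e-04). Heat shock and unfolded protein genes fell in 7 of 26, 16 when adjusted over the list alone (camera adjusted p = 3.13e-16, adjusted p = 0.125 with an estimated correlation), Calr by -0.39 ± 0.06 (adjusted p = 4.82e-04). Gpr165 (-1.69 ± 0.23, adjusted p = 7.92e-05) fell as it did in females, and Apoe differed by -0.11 ± 0.31 (adjusted p = 0.962). The count of 222 was 122 without young adult male 3, 124 without young adult male 2, 144 without middle-aged male 4 and 103 when only these libraries were fitted.

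Whether the sexes change alike with age was asked from genes called in both. From young adulthood to old age 563 genes changed in the same direction in females and males, against 132 for independent lists, and 23 in opposite directions. From young adulthood to middle age the number was 117 against 11.95, with 2 opposite. From middle to old age it was 49 against 13.3, with 16 opposite, and the 49 became 8 without aged female 1, aged male 1 and middle-aged female 2, with aged male 4, the library highest in S100a9, kept. Across the tested genes, which are not independent replicates, the log2 fold changes of the sexes had a Pearson r of 0.401 from young to old, 0.350 from young to middle age and 0.115 from middle to old age (Spearman 0.313, 0.238 and 0.0547). The levels of single genes per library show the shared rise of Apoe, Cst7 and Cd74 in old age.

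**Figure D4:**
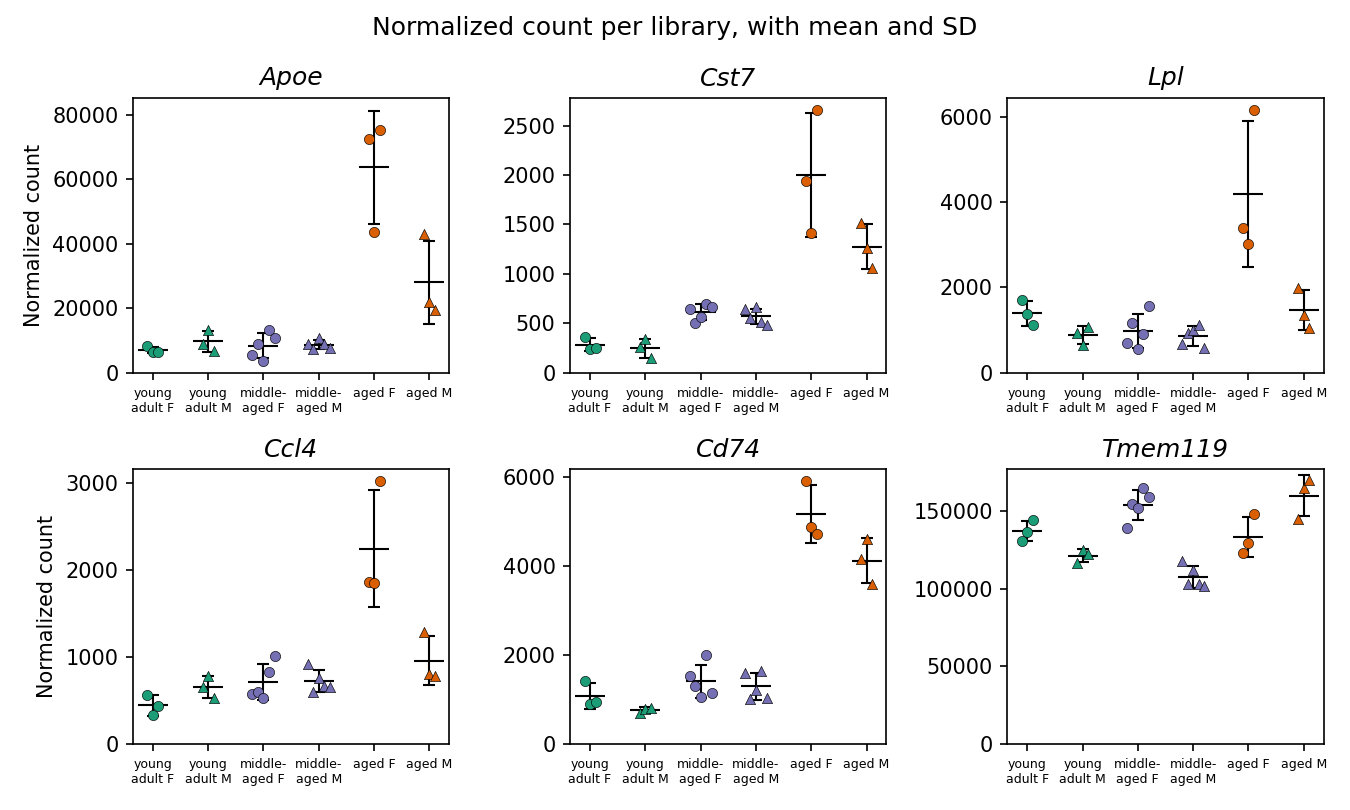
Normalized counts of 6 genes in each library by group (F, female; M, male), with the group mean and SD as bars. Apoe averages 63743 in aged females and 28044 in aged males, and between 6992 and 9680 in the 4 younger groups.

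How females and males differ at each age was asked next. In young adults 994 genes were higher and 1035 lower in females. Lysosomal genes were higher in 23 of 41 cases, 27 when adjusted over the list alone (camera adjusted p = 2.03e-11, adjusted p = 0.277 with an estimated correlation). The membrane protein Lamp2 was higher by 0.77 ± 0.11 (adjusted p = 6.60e-05). Genes of oxidative phosphorylation were higher in 20 of 73, 27 when adjusted over the list alone (camera adjusted p = 1.59e-11, adjusted p = 0.277 with an estimated correlation), Atp5a1 by 0.69 ± 0.07 (adjusted p = 2.59e-06). Females had lower clock genes in 7 of 17 cases on both counts (camera adjusted p = 0.00763, adjusted p = 0.227 with an estimated correlation), Per1 at -1.87 ± 0.35 (adjusted p = 7.31e-04) and Per3 at -1.54 ± 0.24 (adjusted p = 1.64e-04). Of 18 immediate early genes 4 were lower and 1 higher, 5 and 1 when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.277 with an estimated correlation), Ier2 at -1.53 ± 0.21 (adjusted p = 4.34e-05). The complement receptor gene C3ar1 (0.59 ± 0.12, adjusted p = 0.00174), the X-linked receptor gene Gpr34 (0.53 ± 0.11, adjusted p = 0.00161), Cd9 (0.76 ± 0.10, adjusted p = 2.27e-05) and P2ry12 (0.51 ± 0.10, adjusted p = 0.00121) were higher in females. Apoe differed by -0.42 ± 0.34 (adjusted p = 0.445). Hist1h2ac stood at 118 ± 4.39 normalized counts in males and 1.013 ± 1.75 in females.

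Genes higher in young adult females had a median transcript length of 2879 bases and genes lower 4632. Values did not overlap between the sexes for 32.4% of genes (chance gives 10%). The count of 2029 was 1119 without young adult male 2, 1347 without young adult female 4 and 1180 when only the 6 libraries were fitted. Rescaling to equal totals moved the median of all genes by -0.15 and gave 396 higher and 1643 lower, with 11 lysosomal and 5 oxidative phosphorylation genes higher.

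At middle age, with 5 libraries per sex, 1319 genes were higher and 1382 lower in females. Homeostatic genes were higher in 15 of 24 cases and lower in 1 on both counts (camera adjusted p = 2.40e-08, adjusted p = 0.0658 with an estimated correlation). Tmem119 was higher by 0.52 ± 0.07 (adjusted p = 4.69e-06), Fcrls by 0.59 ± 0.07 (adjusted p = 2.00e-06), Olfml3 by 0.57 ± 0.06 (adjusted p = 4.11e-07) and the hexose transporter Slc2a5 by 0.66 ± 0.07 (adjusted p = 7.85e-07). Lysosomal genes were higher in 33 of 41, 36 when adjusted over the list alone (camera adjusted p = 3.43e-19, adjusted p = 0.0658 with an estimated correlation), the glucosidase Gaa by 0.69 ± 0.08 (adjusted p = 9.85e-07). Complement genes were higher in 7 of 13 on both counts (camera adjusted p = 9.86e-04, adjusted p = 0.147 with an estimated correlation), C3ar1 by 0.60 ± 0.09 (adjusted p = 4.64e-05) and C1qa by 0.57 ± 0.07 (adjusted p = 5.08e-06). So were disease-associated genes in 10 of 26, 12 when adjusted over the list alone (camera adjusted p = 9.26e-05, adjusted p = 0.313 with an estimated correlation). Lars2 was 1.63 ± 0.14 higher in females (adjusted p = 2.45e-08). Nfkbiz (-2.30 ± 0.30, adjusted p = 7.47e-06), the interferon-induced Mx1 (-3.01 ± 0.52, adjusted p = 1.55e-04) and Snhg17, a host of small nucleolar RNAs (-3.33 ± 0.54, adjusted p = 8.00e-05), were lower in females, and Apoe differed by -0.19 ± 0.27 (adjusted p = 0.675). The median transcript length was 2892.5 bases for genes higher and 4559 for genes lower in females. Values did not overlap between the sexes for 16.1% of genes, where chance gives 0.794%. Rescaling to equal totals, with the median of all genes moved by -0.16, gave 469 higher and 2427 lower, with 25 lysosomal genes higher and 11 homeostatic genes higher against 3 lower.

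In old age 24 genes were higher and 30 lower in females, 4 of the latter the Y-linked genes. Among those higher were Lpl (1.49 ± 0.33, adjusted p = 0.041), the chemokine gene Ccl4 (1.23 ± 0.25, adjusted p = 0.0263), Csf1 (0.96 ± 0.22, adjusted p = 0.0455) and Cd83 (0.82 ± 0.14, adjusted p = 0.00925). So were lysozyme Lyz2 (0.92 ± 0.19, adjusted p = 0.0263), the cytokine receptor chain Il2rg (1.01 ± 0.21, adjusted p = 0.0303), C3ar1 (0.60 ± 0.12, adjusted p = 0.0263) and Gpr34 (0.54 ± 0.11, adjusted p = 0.0263). The lipoprotein receptor Lrp1 was lower (-0.82 ± 0.16, adjusted p = 0.0225). The mitotic checkpoint kinase Bub1 had 0 reads in aged females and 71.3 ± 32.4 normalized counts in aged males. Apoe (1.23 ± 0.34, adjusted p = 0.104) and Clec7a (0.91 ± 0.25, adjusted p = 0.104) did not pass. Of the disease-associated genes 2 of 26 were higher, and 14 when adjusted over the list alone (camera adjusted p = 2.71e-10, adjusted p = 0.0874 with an estimated correlation). The inflammatory list had 2 of 22 higher, and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.00874 with an estimated correlation). Proliferation genes were lower in 1 of 30, 6 when adjusted over the list alone (camera adjusted p = 4.97e-06, adjusted p = 0.148 with an estimated correlation).

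These 54 calls rested on few libraries. The count was 16 without aged female 1, 20 without aged male 2, 26 without aged male 1 and 98 without aged male 4. It was 8 when only the 6 libraries were fitted and 12 without the 3 libraries that stand apart. Without aged female 1, Lpl (adjusted p = 0.0967), Ccl4 (0.0629), Csf1 (0.149), Cd83 (0.0736), Lyz2 (0.142), Il2rg (0.134), C3ar1 (0.125), Gpr34 (0.0973) and Lrp1 (0.0629) did not pass. Each of these genes also lost its call without at least 1 of the other aged libraries, Cd83 (adjusted p = 0.0619) and Lyz2 (0.095) without aged male 2 and Lrp1 (0.0762) without aged male 1. The others had adjusted p from 0.0529 (C3ar1 without aged female 3) to 0.13 (Csf1 without aged male 2). None of the 9 passed when only the 6 libraries were fitted, and without the 3 libraries that stand apart only Ccl4 did. With replicate number as a block the calls of Lpl, Csf1, C3ar1, Gpr34 and Lrp1 were lost, with no filter those of Lpl and Csf1, with edgeR that of Csf1, and with the length and GC trend removed those of Lpl and Gpr34.

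Averaged over the ages, 1609 genes were higher and 1733 lower in females. Of the comparisons averaged, those in young adults and at middle age cross the gap on the first component. That in old age, with 54 genes called, does not. At all 3 ages 18 genes were called, 14 of them in the same direction, and these 14 are named for that reason, after their values were seen. Both counts draw on the 54 calls of old age, which were 16 without aged female 1. C3ar1, Gpr34, Il2rg, the lysosomal membrane gene Mfsd1, the ubiquitin ligase gene Rnf128, Xist and its antisense Tsix were higher in females throughout, and Lrp1, Dido1, Nav3, Ddx3y, Eif2s3y, Kdm5d and Uty lower. With the transcript length and GC trend removed, Lrp1 in young adults was at -0.10 (adjusted p = 0.634) and did not pass. C3ar1 had 0.59, 0.60 and 0.60 and Gpr34 0.53, 0.41 and 0.54 from young to old, with averages of 0.60 ± 0.06 (adjusted p = 7.09e-07) and 0.49 ± 0.06 (adjusted p = 1.97e-06). Lyz2 was lower in females at the younger ages (-0.79 and -0.73) and higher in old age (0.92). On average, 34 of 41 lysosomal genes were higher in females on both counts (camera adjusted p = 7.74e-19, adjusted p = 0.0654 with an estimated correlation). Of the disease-associated genes 18 of 26 were higher, 20 when adjusted over the list alone (camera adjusted p = 1.11e-09, adjusted p = 0.119 with an estimated correlation). Class I presentation had 9 of 13 higher on both counts (camera adjusted p = 7.81e-04, adjusted p = 0.307 with an estimated correlation), H2-D1 by 0.47 ± 0.10 (adjusted p = 0.0014). The proliferation marker Mki67 was lower by -3.53 ± 0.54 (adjusted p = 4.12e-05). Rescaling to equal totals moved the median of all genes by -0.11 and gave 644 higher and 2789 lower. The same rescaling left fewer lysosomal genes higher at both younger ages, as given above.

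Differences between the sexes in the change with age were tested directly. In the steps that end in old age the male change crosses the gap on the first component and the female change does not. A sex difference in the change with age cannot be told apart from that gap there. From young adulthood to old age the change differed toward females, with a higher value in females than in males, in 186 genes and toward males in 165. The chemokine genes Ccl3 (difference 1.90 ± 0.39, adjusted p = 0.0108) and Ccl4 (1.80 ± 0.36, adjusted p = 0.00965) differed toward females, as did Lyz2 (1.72 ± 0.27, adjusted p = 0.00154). Zfp36 (1.53 ± 0.18, adjusted p = 1.58e-04) and Ier2 (1.72 ± 0.30, adjusted p = 0.00307) differed in the same direction, and Per3 by 1.62 ± 0.35 (adjusted p = 0.0127), which was 0.0522 without young adult male 2 and also lost its call without the 3 libraries that stand apart or when only these groups were fitted. Apoe differed by 1.66 ± 0.49 (adjusted p = 0.0626), and passed with replicate number as a block, after rescaling to equal totals, with the length and GC trend removed, and in the fits without young adult male 4, aged female 2 or aged male 1. Inflammatory genes had 3 of 22 members toward females and 1 toward males, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00836, adjusted p = 0.242 with an estimated correlation). Homeostatic genes had 6 of 24 toward males, 8 when adjusted over the list alone (camera adjusted p = 6.18e-04, adjusted p = 0.271 with an estimated correlation). Olfml3 had -0.59 ± 0.11 (adjusted p = 0.00486). The count of 351 was 131 without young adult male 2, 196 without young adult female 4, and 228 and 209 without aged females 1 and 3. It was 129 when only these groups were fitted. Rescaling to equal totals, with the median of all genes moved by 0.12, gave 315 and 71.

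From middle to old age the change differed in 476 genes toward females and 424 toward males. Here too only the male change crosses the gap on the first component. Homeostatic genes lay toward males in 11 of 24 cases, 13 when adjusted over the list alone (camera adjusted p = 3.89e-08, adjusted p = 0.132 with an estimated correlation). Examples are Tmem119 (-0.78 ± 0.11, adjusted p = 1.49e-04), Slc2a5 (-0.90 ± 0.12, adjusted p = 1.21e-04) and Olfml3 (-0.75 ± 0.10, adjusted p = 8.56e-05). Lars2 (-2.13 ± 0.23, adjusted p = 2.41e-05) and C1qa (-0.53 ± 0.12, adjusted p = 0.00735) lay the same way, and Lyz2 (1.65 ± 0.24, adjusted p = 2.30e-04), Zfp36 (1.16 ± 0.16, adjusted p = 1.49e-04) and Nfkbiz (3.49 ± 0.50, adjusted p = 2.01e-04) the other. Apoe differed by 1.42 ± 0.43 toward females at an adjusted p of 0.0476. That call was lost in 12 of the 16 fits without 1 library (adjusted p up to 0.134, without aged male 4) and with edgeR, DESeq2, a pseudocount of 0.25, no filter, only the groups compared, and without the 3 libraries that stand apart. Inflammatory genes had 8 of 22 toward females and 1 toward males, 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.306 with an estimated correlation). The 900 genes became 569 without the 3 libraries that stand apart and 579 with replicate number as a block. Rescaling to equal totals, with the median of all genes moved by 0.14, gave 748 and 161, with 6 homeostatic genes toward males and 1 toward females.

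Between young adulthood and middle age the change differed toward females in 33 genes and toward males in 16. The immune checkpoint gene Lag3 (1.85 ± 0.23, adjusted p = 1.96e-04), the adrenergic receptor gene Adrb1 (1.82 ± 0.28, adjusted p = 0.00135), Lars2 (1.60 ± 0.23, adjusted p = 7.78e-04), Stab1 (1.13 ± 0.16, adjusted p = 7.78e-04) and Tgfb1 (0.83 ± 0.15, adjusted p = 0.013) differed toward females. Without young adult female 1 the count was 22 and Tgfb1 had an adjusted p of 0.0571. The count was 30 without middle-aged male 4, 81 with no filter on low values, 240 with DESeq2 and 24 with the length and GC trend removed.

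Lists of markers of T and NK cells, B cells and erythroid cells had fewer than 3 members tested, and several markers of macrophages, monocytes and neutrophils are not analysed here. From middle to old age in males 5 of 7 neutrophil markers rose on both counts (camera adjusted p = 0.00313, adjusted p = 0.332 with an estimated correlation). S100a9 had an adjusted p of 0.0224 there, 0.133 without aged male 1 and 0.136 without aged male 4, and did not pass with replicate number as a block. Of 9 markers of border-associated macrophages 5 were higher in aged than in young adult females, 7 when adjusted over the list alone (camera adjusted p = 4.11e-04, adjusted p = 0.136 with an estimated correlation). So were 2 of 5 monocyte markers on both counts (camera adjusted p = 0.00745, adjusted p = 0.163 with an estimated correlation). Astrocyte markers had 2 of 11 higher there, 3 when adjusted over the list alone (camera adjusted p = 0.179), neuronal markers 1 of 8 on both counts (camera adjusted p = 0.991) and endothelial and pericyte markers 1 of 9 on both counts (camera adjusted p = 0.335).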

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

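The splits of the samples, the distance of single libraries from their group and the differences between the sexes were planned, whereas the tests of length and GC content, depth, library preparation, retinal reads, Y-linked reads, depth of a single library and genes that escape X inactivation were chosen only after the result was seen.

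The 8 libraries of young adult and middle-aged males lay apart from the other 14, and the comparisons across that gap held most of the calls. Depth is argued against, since 94.7% of the calls between the sexes in young adults and 94.0% at middle age were kept in the same direction after thinning to 1 depth. Bias by transcript length and GC content stays open. With that trend removed 73.5% of the calls in young adults (1460 of 1986) and 76.0% at middle age (1996 of 2627) were kept. In males 67.5% (1274 of 1888) were kept from middle to old age and 82.2% (1706 of 2075) from young adulthood to old age. The trend may therefore account for part of the pattern. Preparation in batches cannot be told apart from the groups, because no group has libraries on both sides, although 16 of 20 histone genes, whose transcripts mostly lack a poly(A) tail, were higher in middle-aged males and none in females; a difference of sex that ends in old age also stays open, untested.

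The rod gene Gnat1 stood at 118 or more normalized counts in the 3 young adult females and at most 0.987 elsewhere. If retinal tissue had entered the samples, other photoreceptor genes should be high as well, and 10 of the 17 others tested were higher in young adult than in aged females. Prph2 and Pdc averaged 33.1 and 23.5 normalized counts there and 0 in all other groups, whereas Sag reached 28.6 in middle-aged female 5 (at least 52.5 in young adult females) and Pde6g was at 10.4 or more in young adult males (at least 10.1 in the females), and Gnb1 (4211 against a mean of 4218 elsewhere), Rom1 (29.7 against 35.1), Guca1a (141 against 105), Guca1b (6.04 against 8.28), Rdh12 (69.5 against 54.1), Pde6b and Abca4 did not pass. Testing needed 10 or more normalized counts in at least 3 libraries. Prph2, Pdc, Pde6a, Rbp3 and Rp1, among others, reached this through the young adult females alone, with at most 2.55 elsewhere. The filter thus admitted them through the same libraries that the prediction is about. The share of 10 of 17 leans toward the prediction, but the filter fixed part of it, so it cannot decide the prediction. The list was written after photoreceptor transcripts were seen, and the sort for CD11b should remove such cells, so RNA carried over from retina is a candidate explanation for the members that passed, not for all. No biological explanation was tested.

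Xist stood at 42.4 normalized counts in middle-aged female 2. A male library in its place is argued against, since it held 0 reads of 4 Y-linked genes where the lowest middle-aged male held 5379. Low depth is argued against too, since its depth was 1.09 times the lowest of the other middle-aged females. Of 6 genes that escape X inactivation 5 were lowest in this library (exact binomial p = 0.0016, one-sided), with a median log2 ratio of -0.38 to the other 4 libraries against -0.25 for middle-aged males. That test counts 6 genes of 1 library as independent trials, so its p-value does not measure the spread between samples. Ddx3x (5604 against 5631 in the next lowest) and Eif2s3x (48.1 against 51.3) were lowest by little, Kdm6a (537 against 1081) by more. Loss of 1 X chromosome in this sample may be considered only as a hypothesis found and tested on the same data.

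For each count of genes, other splits of the same libraries were fitted. Chance is excluded for females against males at middle age (2701 genes, 1 of 100 splits as large, highest other 436) and for their average over ages (3342, 1 of 100, highest other 225). It is also excluded, at 1 of 56 splits each, for middle-aged against young adult females (1189, highest other 4) and aged against middle-aged females (173, highest other 2). The same holds for middle-aged against young adult males (222, highest other 30) and aged against middle-aged males (1937, highest other 100). A share of 1 of 56 is the lowest that these splits can give. All the splits take libraries as independent, which the labels do not settle. Nor do they show that a count is stable, and the 173 was 21 without aged female 1. Groups of 3 against 3 give 10 splits, too few for a share under 0.05, with the real split highest in each case. The real counts there were 2029 between the sexes in young adults (highest other 2), 54 in old age (highest other 5), 1525 between aged and young adult females (highest other 3) and 2124 in males (highest other 83). Chance is not excluded for the difference between the sexes from young adulthood to middle age (49 genes, 6 of 100 splits as large, highest other 785) or to old age (351 genes, 12 of 100, highest other 1652). All 5 and all 11 of the other splits as large part the sexes fully at 1 age, and the highest count without such an age was 1 in each, so these splits point to the structure of the samples by sex within an age. From middle to old age the difference between the sexes held 900 genes (1 of 100 splits as large, highest other 860). That 860 came from a split that parts the sexes fully at 1 age, and the highest without such an age was 4. Chance is not called excluded there, because a count of nearly that size follows from parting the sexes at 1 age.

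A library lay far from the other 4 of its group in 26 of 267 pairs of gene and group tested, where the nominal rate of the test gives 13.4. That rate holds for independent pairs and normally distributed values. These are unlogged counts of genes that were picked, and genes of 1 library can move together, so the rate does not measure chance here. The number beside each gene is its gap to the nearest library divided by the range of the group. In middle-aged females, number 2 was highest for the neutrophil genes S100a9 (0.998), Ltf (0.995) and Lcn2 (0.992) and lowest for Kdm6a (0.803). Number 6 was highest for Mmp12 (0.733) and Kl (0.972) and lowest for Calr (0.771), number 5 highest for Gpnmb (1) and Bub1 (0.724), and number 3 highest for Snhg17 (0.781), Gnat1 (1) and Hist1h2ac (1). In middle-aged males, number 3 was highest for Ifit3 (0.783), Cd83 (0.767), Ctsb (0.945), Lamp1 (0.834), Rsad2 (0.799) and Mx1 (0.712) and lowest for Lime1 (0.766), Lrp1 (0.745) and Snhg17 (0.712). Number 5 was lowest for Csf1 (0.772) and highest for Gpnmb (1), number 1 highest for Gadd45g (0.718), and number 2 highest for S100a9 (1). Where the number is 1, the other 4 libraries had 0 reads and the 1 library may hold few, with Gnat1 at 0.693, S100a9 at 0.61, Hist1h2ac at 2.77 and Gpnmb in females at 3.18 normalized counts. Of the 260 pairs with a library at 10 or more, 21 were far from the others, where the nominal rate gives 13, with the same limit.

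Among the genes taken forward for the age changes, the change with age differed between females and males by the test of that difference in 49 cases, a part of the genes called over all, given here, where reported, as log2 change in females minus that in males. From young adulthood to middle age these were Tgfb1 (0.83), Stab1 (1.13), Lag3 (1.85), Adrb1 (1.82), Lars2 (1.60), Cd9 (-0.57) and Gnat1 (-7.04). From middle to old age, females had the higher value for Apoe (1.42), Lpl (1.35), Ccl4 (1.29), Ccl3 (1.21), Cd83 (0.59), Zfp36 (1.16), Nfkbiz (3.49), Hist1h2ac (5.32), Lime1 (3.71), Lyz2 (1.65) and Tnf (4.11). The value of Tnf was 2.08 without the 3 libraries that stand apart. Males had the higher value in that step for Sall1 (-0.50), Fcrls (-0.58), Olfml3 (-0.75), Lars2 (-2.13), Trem2 (-0.49), C1qa (-0.53), Man2b1 (-0.42), Gaa (-0.54), Tmem119 (-0.78), Slc2a5 (-0.90), Selplg (-0.69), Pkm (-0.42) and Hk2 (-0.70). From young adulthood to old age, females had the higher value for Rab7b (4.58), Ccl4 (1.80), Ccl3 (1.90), Per3 (1.62), Tef (0.81), Atf4 (0.62), Hist1h2ac (5.83), Dnmt3b (3.69), Zfp36 (1.53), Ier2 (1.72) and Lyz2 (1.72). Males had the higher value there for Olfml3 (-0.59), Tmem119 (-0.44), Cadm1 (-0.55), Cd44 (-4.21) and Gnat1 (-7.52). Gnat1, Hist1h2ac and Rab7b had 3 reads or fewer in at least 1 group, so their values depend on the pseudocount and are no measure of size. In the steps that end in old age only the male change crosses the gap between the libraries.

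Of these 49 differences 22 were called in every setting and 27 lost the call in at least 1, with none reversed. In more than 50% of the fits without 1 library the call was lost for 10 of them. From young adulthood to middle age this was Cd9 (9 of 16 fits). From middle to old age it was Apoe (12 of 16), Cd83 (12), Tnf (11), Pkm (11) and Lpl (10), and from young adulthood to old age Tmem119 (10 of 12), Atf4 (10), Tef (8) and Cd44 (8). Each of these 10 also lost the call in at least 2 other settings. In the first step Tgfb1 and Gnat1 lost it in at least 1 setting as well. So did Ccl4, Ccl3, Sall1, Trem2, Man2b1, Gaa, Hk2 and Lime1 in the step from middle to old age, and Rab7b, Per3, Cadm1, Hist1h2ac and Dnmt3b from young adulthood to old age.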

How the results depend on the processing

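The settings without the 3 libraries that stand apart, with the transcript length and GC trend removed and with reads thinned to 1 depth were chosen only after the result was seen. Of the counts of genes and of agreement, 117 stayed within 1.5 times under the planned settings other than leaving out a library and 23 did not, and under the added settings 42 did and 6 did not. The causes of these changes were not tested. Fewer libraries alone need not account for them, since the counts also depended on which single library was left out, as given below. Fitting only the groups compared, with fewer libraries, gave 1180 genes between the sexes in young adults, 8 in old age, 902 for aged against young adult females, 103, 1137 and 696 for the steps from young to middle age, middle to old age and young to old age in males, and 129 for the difference between the sexes from young to old. DESeq2 gave 203 between the sexes in old age, 370 for aged against middle-aged females, 412 for middle-aged against young adult males, 240 and 706 for the differences between the sexes from young to middle age and from young to old, and agreements of 184 from young to middle age and 94 from middle to old age. With replicate number as a block there were 20 between the sexes in old age, 792 and 52 for the first and the second age step in females, 22, 579 and 200 for the differences between the sexes from young to middle age, middle to old age and young to old, and an agreement of 28 from middle to old age. edgeR gave 35 between the sexes in old age. Without a filter the difference between the sexes from young to middle age was 81, and with the length and GC trend removed 24. Without the 3 libraries that stand apart there were 12 between the sexes in old age and 27 for aged against middle-aged females. In that fit the differences between the sexes held 569 genes from middle to old age and 209 from young to old. The agreement from middle to old age was 8.

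Leaving out 1 library at a time gave 1119 to 1753 genes between the sexes in young adults, 2142 to 2665 at middle age, 16 to 98 in old age and 2794 to 3476 on average. In females it gave 636 to 1074 from young to middle age, 21 to 147 from middle to old age and 956 to 1234 from young to old, and in males 122 to 248, 1358 to 1925 and 1241 to 2066. The differences between the sexes ranged from 22 to 62, 626 to 959 and 131 to 424. The lowest values came without aged female 1 (16, 21, 956 and 626), young adult male 2 (1119, 2794, 1241 and 131), young adult female 4 (636), young adult female 1 (22), young adult male 3 (122), middle-aged male 2 (2142) and aged male 1 (1358). Of the 346 gene values taken forward 330 were called; 230 of these were called in every setting and 100 lost the call in at least 1, 11 of them only when a library was left out. Of 16 not called, 4 were called in at least 1 setting. No value changed sign where the main fit or the setting called it, though some values called in neither did change sign. The 170 list calls were each tested again under several settings, and over these repeats the call was kept 973 times and lost 217 times. With an estimated correlation many of the list calls were lost, as the values printed beside them show. Thinning to 1 depth kept 94.7% of the calls between young adult females and males and 94.0% at middle age, so depth limited few of these.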

Other observations

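The tests on the lists of histone genes, small nucleolar RNA hosts and choroid plexus genes, which were written after members had been seen, were chosen only after the result was seen, and all other lists here were planned.

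Metabolic and uptake genes also differed between the sexes on average over the ages. This average draws on the young adult and middle-aged comparisons, which cross the gap on the first component. Cholesterol biosynthesis had 9 of 23 members higher in females on both counts (camera adjusted p = 1.80e-04, adjusted p = 0.0654 with an estimated correlation), and 5 higher after rescaling to equal totals. Glycolysis had 11 of 20 higher on both counts (camera adjusted p = 1.01e-04, adjusted p = 0.119 with an estimated correlation), or 8 higher and 1 lower after rescaling. Phagocytic and scavenger receptors had 14 of 24 higher and 2 lower, 15 and 2 when adjusted over the list alone (camera adjusted p = 7.58e-04, adjusted p = 0.104 with an estimated correlation), or 5 and 2 after rescaling. The list of X-linked genes that escape inactivation, which includes Xist, had 5 of 7 higher in females on both counts, Xist among them (camera adjusted p = 0.00136, adjusted p = 0.119 with an estimated correlation). In old age the 1 of these 7 that passed was Xist, and 4 passed, Xist included, when adjusted over the list alone (camera adjusted p = 1.09e-06, adjusted p = 0.0228 with an estimated correlation). The list was not tested without Xist.

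Further lists were compared between aged and young adult females. Receptors of the toll-like family and inflammasome genes had 8 of 25 higher and 1 lower, 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0387, adjusted p = 0.16 with an estimated correlation). Genes of the oxidative stress response had 4 of 26 higher, 5 when adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.196 with an estimated correlation). TGF-beta signalling had 3 of 18 higher and 1 lower, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0548). Senescence and p53 target genes had 2 of 21 higher and 2 lower, 3 and 3 when adjusted over the list alone (camera adjusted p = 0.979). Glucocorticoid-responsive genes had 1 of 14 higher and 3 lower, 3 and 3 when adjusted over the list alone (camera adjusted p = 0.497). Of the steroid and sex hormone receptors 1 of 9 was lower on both counts (camera adjusted p = 0.348), and no oligodendrocyte marker of 7 passed (camera adjusted p = 0.723).

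Groups of transcripts beyond the planned lists were counted as well. Of 20 histone genes 15 were lower in young adult and 16 in middle-aged females than in males of the same age, and none in old age, where 54 genes were called in all. Of 14 host genes of small nucleolar RNAs 7 and 10 were lower, and again none in old age. Choroid plexus genes varied from library to library, with Ttr between 0 and 4342 normalized counts and highest in aged male 1, and 7 of 13 members were lower in females on average. Lars2 lay between 18951 and 30963 normalized counts in middle-aged females and at 20737 in aged male 1, against at most 12143 in every other library.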
